A study of Ginkgo biloba with 7 samples.

How the data were processed

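Ovules of Ginkgo biloba, a dioecious gymnosperm whose receptive ovules exude a pollination drop that catches airborne pollen, were sampled at 2 stages from several trees of one cultivar, per the labels' protocols. The first stage, PD, was the mature ovule secreting its drop, and the second, PN, was the pollinated ovule at 1 day after pollination. The series holds 7 samples, of which 4 are RNA-seq libraries (2 labelled per stage), 2 are small RNA libraries (1 per stage), and 1 is a mix of ovules at 2 stages of development. The mixed sample was taken here to be the degradome library, because the series names degradome sequencing (sequencing of cleaved RNA ends) and this sample carries the list of miRNA targets.

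The gene table holds FPKM values (fragments scaled to gene length and library size) that the authors computed, 1 value per gene and library, per the file headers. TopHat2 2.0.12, Cufflinks 2.1.1, TopHat and Bowtie are named in the submitters' processing notes. The genome build, the annotation and any filter are not given in the sources used here. The table has 4 columns of values. Its headers name PD1 and PN1 once each, while 2 columns carry the same name, PD2, and none is headed PN2. The name alone cannot tell which of these 2 columns belongs to which sample, so 2 columns were not used in any step. The gene comparison therefore set 1 PD library against 1 PN library. The moderated test in limma, its replicate block, the leave-one-out fits and the gene set tests fixed before the data were examined could not be used, since they need replicates and only 1 library per stage could be matched to a column by its name. Descriptive comparisons without p-values took their place. The 2-fold limit as the sole rule for genes and the comparison of target lists with random lists were therefore chosen after the files had been seen.

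FPKM values do not give the absolute depth. At low expression a gene's FPKM moves in steps of 1 fragment, so the ratio of steps gives the relative depth of both libraries. Over 2379 genes above 0 in both libraries and under 0.5 FPKM, the commonest ratio placed 1 fragment of the PN library at 0.848 times its worth in the PD library, a relative depth of 1.18. Of these genes, 63.8% had a ratio within 1% of a ratio of whole numbers up to 4 after this correction. Genes with a mean FPKM of at least 1 over both libraries were compared as log2(FPKM + 1), a scale that understates the change of genes near the pseudocount of 1. A gene was described as higher or lower at a difference of at least 1 on this scale, a 2-fold change.

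The gene IDs are not paired with gene names or descriptions in the files, and no reference annotation was used here. The functional gene lists defined by name (such as sugar transport, cell wall, hormone and pollen genes) could not be formed and gave no result. The rule for named genes therefore reduced to the 2 genes with the largest increase and the 2 with the largest decrease. Its part on target genes ranked by p-value could not be applied. The lists that remained were the targets of each miRNA family, a family being all names with the same number.

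The small RNA table gives read counts per miRNA name, deposited as whole numbers without normalization, and a TPM value. The deposited TPM equals the read count scaled to the sum of all reads counted in the same table, to within 4.95e-05. The table does not say how reads were assigned to names. Of the 127 names with at least 50 reads over both libraries, 26 share their exact counts in both libraries with another name, so some reads are probably counted under several names. Sums over a family would then hold repeated reads, with shares that grow with the number of its names and intervals that are too narrow. Shares were taken of all counted reads, 774387 in PD and 1129198 in PN. Ratios of shares have exact conditional binomial (Clopper-Pearson) 95% intervals, and single shares have exact Clopper-Pearson intervals. These intervals and the limit for a count of 0 (3 reads, or a TPM of 3.87 in PD and 2.66 in PN) cover counting error only, not variation between ovules or library preparations. Names with at least 50 reads, a ratio of at least 2 in either direction and an interval excluding 1 were described as higher or lower. The rule for named miRNAs took up to 10 in each direction by the size of the ratio, plus the 5 with most reads in each library.

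The target table pairs miRNA names with gene IDs and holds no category, p-value or read count. Of its 1092 rows, 8 repeat another row, which left 1084 pairs. Target lists with at least 5 compared genes were set against 10000 random lists of the same size, drawn with the same number of genes from each of 20 bins of mean FPKM. The percentile of the list's median among these random lists describes these 2 libraries and is not a p-value. Intervals of the median gene difference are from 1000 bootstrap draws over genes, and intervals of arm ratios use a normal approximation on log counts. Tested on simulated data over 21308 genes with 100 lists of 20 genes each, 4% of unchanged lists, 64% of lists shifted by 0.5 and 100% of lists shifted by 1 (log2) fell outside the middle 95% of random lists. The simulated genes varied independently, and lists of other sizes were not simulated. Ratio intervals simulated for 127 miRNA names held a true ratio of 1 in 95.3% and a true ratio of 2 in 95.8% of 2540 draws. These draws were independent counts per name, the model on which the interval rests, so they check the calculation only. Reads repeated under several names and family sums were not simulated.

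Alternatives were other pseudocounts, other filters on FPKM and reads, median-of-ratios and quantile scaling, the TPM values, shares without the most abundant name, a lower fold limit for families, a single name per family, identical names counted once, and equal sums without the 10 most abundant genes. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.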

Results

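The data describe ovules of Ginkgo biloba while they secreted the pollination drop (PD) and 1 day after pollination (PN). Gene expression was compared between 1 RNA-seq library per stage. The table listed 43456 genes, of which 27099 were above 0 FPKM in the PD library and 27545 in the PN library. miRNA abundance was compared between 1 small RNA library per stage, with 774387 and 1129198 reads counted to 279 miRNA names. The sample of mixed ovules, taken here to be the degradome, supplied the list of miRNA targets. With 1 library per stage in each assay, no value below has a replicate error, and differences are between libraries rather than tested differences between stages.

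The first comparison concerned which genes differed between secreting and pollinated ovules, the question set by the study's title on how drop secretion is regulated. Most genes were expressed at similar levels at both stages. Of 21308 genes compared, 83.9% lay within 2-fold, while 1976 were at least 2-fold higher and 1462 at least 2-fold lower in the PN library. The gene with the largest decrease, Gb_31001, was listed at 838 FPKM in PD and 0.263 FPKM in PN, a 664-fold lower value on the FPKM + 1 scale. Gb_24476 was among the most abundant transcripts of the PD library at 6232 FPKM and stood at 28.2 FPKM in PN, 214-fold lower. The largest increases were those of Gb_32816, from 0.347 to 122 FPKM (91.1-fold), and Gb_06117, from 3.48 to 234 FPKM (52.4-fold). All 4 folds are on the FPKM + 1 scale and depend on the pseudocount. With a pseudocount of 0.1 the log2 difference went from -9.38 to -11.17 for Gb_31001 and from 6.51 to 8.09 for Gb_32816. These genes are not named in the data, and the list of pollen genes could not be formed. Whether RNA of pollen on the pollinated ovules contributed to the increases was therefore not tested. No unpollinated ovules of the second stage were among the samples, so pollination cannot be told apart from the time between the stages.

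**Figure D1:**
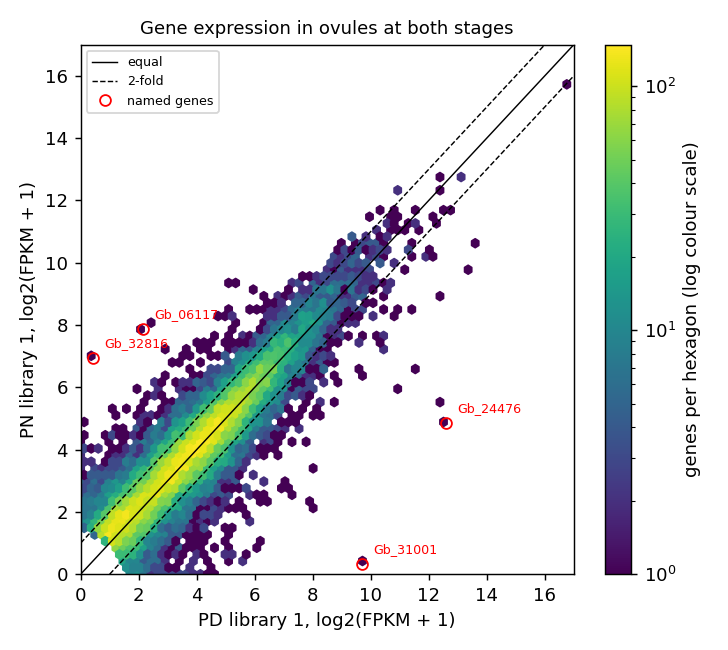
Expression of 21308 genes in the PD library (x axis) and the PN library (y axis), both as log2(FPKM + 1); colour gives the number of genes per hexagon on a log scale, the solid line marks equal values and the dashed lines 2-fold differences. Most genes (83.9%) lie between the dashed lines, and the 4 circled genes are those with the largest decreases and increases.

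Expression was more concentrated in a few transcripts in secreting ovules. The 10 most abundant genes held 16.8% of the summed FPKM in PD and 10.04% in PN, and the single most abundant gene, the same at both stages, held 10.3% (112735 FPKM) and 5.59% (58749.5 FPKM). Across the compared genes, log2(FPKM + 1) correlated between the stages with a Pearson r of 0.912 and a Spearman rho of 0.908; genes are not independent replicates. Genes listed at 0 in a single library numbered 1649 for PD and 1203 for PN. Gene models without the prefix Gb made up 1113 of the compared genes, of which 136 were at least 2-fold higher and 134 at least 2-fold lower in PN, against 1840 higher and 1328 lower among the 20195 models with the prefix Gb. The balance of directions depended on the scaling. The median gene was 0.11 higher in PN on the log2 scale, and 57.5% of the genes beyond 2-fold were higher in PN. Median-of-ratios rescaling, which sets the median near 0 by construction (0.00429 here), gave 1591 higher and 1799 lower genes, or 46.9% higher.

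The second comparison asked which miRNAs differed in abundance. At both stages the reads counted to miRNA names were dominated by miR166, the conserved regulator of class III HD-ZIP transcription factors. Its 24 names held 79.3% of these reads in PD (95% interval 79.2 to 79.3) and 80.6% in PN (80.5 to 80.6). The ratio was 1.02, and 0.992 under median-of-ratios scaling. The factor of that scaling, 1.02445 relative to shares, equals the ratio of gma-miR166u, itself a name of miR166. The scaled value is therefore no separate check. If reads were counted under several names, the shares of miR166 would grow with the number of names, and their intervals would be too narrow. The largest name alone held 17.6% in PD and 18.1% in PN. The most abundant name in both libraries was gma-miR166u, with 136538 and 203966 reads. It was followed in both by ath-miR166a-3p, zma-miR166h-3p, cpa-miR166e and osa-miR166g-3p. Of these, zma-miR166h-3p and cpa-miR166e had almost the same counts. By family sums in PD, miR396, which targets growth-regulating factors in other plants, followed at 3.02% and 3.78% over 21 names. Next was miR167, a regulator of auxin response factors, at 2.96% and 2.40% over 15 names. This order depended on the summing. The single name of miR2950 (17338 and 21928 reads) exceeded the largest name of miR396 (7074 and 14260) and of miR167 (5288 and 6215).

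Of 46 families or single predicted miRNAs with at least 50 reads, 38 were within 2-fold, many of them with intervals that excluded equal shares. Among the conserved developmental families, miR159 (ratio PN over PD 1.003, 95% interval 0.973 to 1.03), miR162 (1.02, 0.984 to 1.06), miR394 (0.954, 0.893 to 1.02), miR156 (1.05, 0.739 to 1.51), miR164 (1.02, 0.796 to 1.32) and miR169 (0.957, 0.778 to 1.18) had intervals that included equality, although the most abundant name of miR162 alone had a ratio of 0.912 and the interval of miR394 was 0.871 to 0.995 under median-of-ratios scaling. Other differences within 2-fold included novel_5 at 0.574 (0.379 to 0.864, on 55 and 46 reads), miR1083 at 0.581 (0.559 to 0.604), miR894 at 0.616 (0.586 to 0.648), novel_3 at 0.707 (0.692 to 0.723) and miR1314 at 0.739 (0.715 to 0.763), all lower in PN. Differences beyond counting error were also seen for miR396 at 1.25 (1.23 to 1.27), miR390 at 1.195 (1.16 to 1.23), miR160 at 1.14 (1.07 to 1.21), miR168 at 1.2004 (1.09 to 1.32) and miR171 at 1.12 (1.03 to 1.204), all higher in PN. miR167 at 0.812 (0.798 to 0.827), miR319 at 0.93 (0.904 to 0.956) and miR172 at 0.63 (0.515 to 0.77), which targets AP2-like floral regulators, were lower in PN. miR858, a regulator of MYB transcription factors, was higher at 1.59 (1.42 to 1.78). miR2118 and miR482, related families known to target disease resistance genes of the NBS-LRR class, had ratios of 1.91 (1.19 to 3.19) and 1.87 (1.02 to 3.65) on few reads, and the interval of miR482 was 0.992 to 3.56 under median-of-ratios scaling. Identical counts point to reads repeated under several names of a family, in which case the family intervals are too narrow. For miR319 the direction depended on how reads were counted: the name with most reads, mtr-miR319a-3p, had a ratio of 1.37, and ath-miR319c one of 0.657. Names of miR396 also went both ways, with ath-miR396b-5p at 1.38 (1.34 to 1.42) and vvi-miR396a at 0.83 (0.79 to 0.87). The miR390 name with most reads, atr-miR390.1, had a ratio of 1.12 (1.07 to 1.18), below that of its family sum.

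Differences of at least 2-fold were seen in 8 families. Lower in PN were miR397 (47 reads in PD and 12 in PN; 5.71-fold lower, 95% interval 2.98 to 11.8), miR408 (1548 and 1081 reads; 2.09-fold lower, 1.93 to 2.26) and miR6478 (2.27-fold lower, 2.07 to 2.498). In other plants miR397 targets laccases and miR408 targets blue copper proteins. miR398, which targets copper/zinc superoxide dismutases and is grouped with these families as a copper-responsive miRNA, went the other way, with 6 reads in PD and 54 in PN (6.17-fold higher, 2.66 to 17.6). The other 4 families higher in PN were miRNAs predicted by the authors under their own labels, novel_33 (7 and 92 reads; 9.01-fold, 4.20 to 23.04), novel_17 (49 and 292 reads; 4.09-fold, 3.01 to 5.65), novel_36 (2.49-fold, 1.26 to 5.39) and novel_29 (2.01-fold, 1.61 to 2.53). Under median-of-ratios scaling novel_29 was below 2-fold, which left 4 families higher. None of the 5 names of miR398 alone reached 50 reads, so its call was lost when families were read by a single name.

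**Figure D2:**
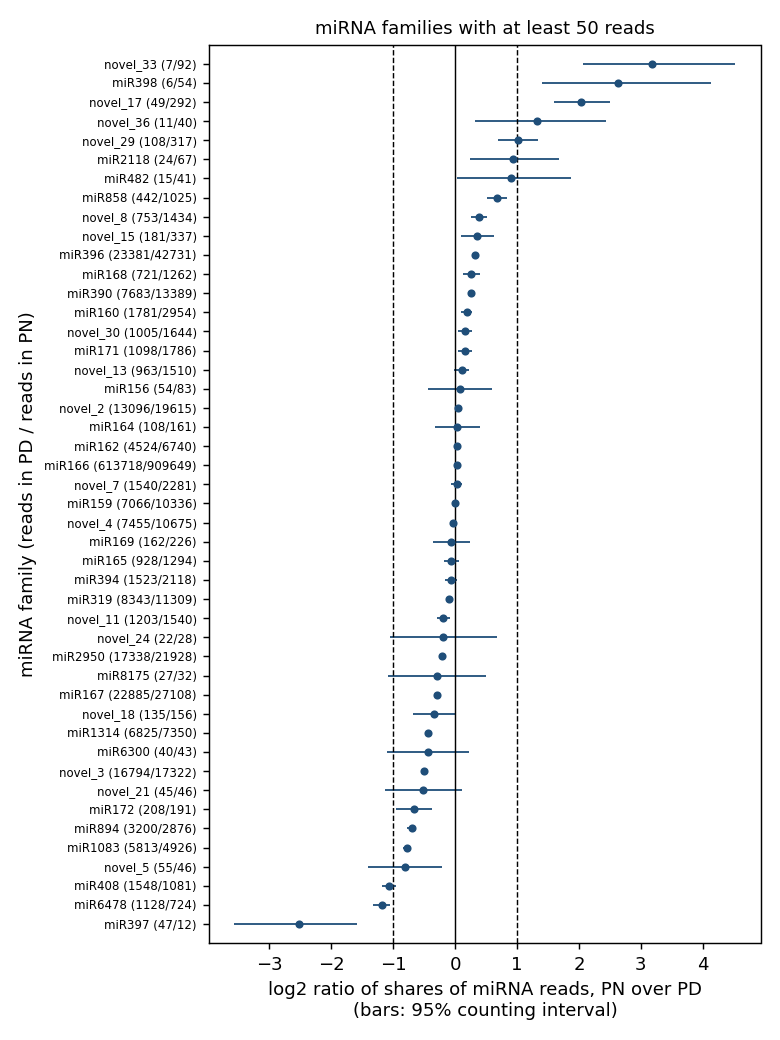
Ratio of the share of miRNA reads in PN to that in PD for the 46 families or single predicted miRNAs with at least 50 reads, on a log2 scale (x axis); points are ratios, bars are exact 95% counting intervals, dashed lines mark 2-fold, and labels give the reads in PD and PN. Most points lie between the dashed lines, with miR397 lowest at 12 reads in PN and novel_33 highest at 92 reads in PN.

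At the level of single names, 11 were at least 2-fold higher and 9 at least 2-fold lower in PN out of 127. The higher names included the less abundant arms of miR390 and miR166. ptc-miR390d-3p went from 86 to 847 reads (6.75-fold, 95% interval 5.41 to 8.53), and ath-miR390a-3p and gma-miR390a-3p shared the same counts of 9 and 42 reads (3.20-fold, 1.54 to 7.48). ath-miR166a-5p was 3.69-fold higher (2.67 to 5.22) and osa-miR166d-5p 3.48-fold higher (3.10 to 3.91). Among the names of miR396, ptc-miR396g-5p was 2.12-fold higher (1.31 to 3.55). Members of miR159 differed in direction although the ratio of their sum was near 1: pde-miR159 was 3.25-fold higher (2.61 to 4.09), while bdi-miR159a-3p was 2.43-fold lower (1.94 to 3.06) and osa-miR159f 2.31-fold lower (1.86 to 2.88). The lower names were otherwise pab-miR397, ptc-miR6478 and 5 names of miR408 with 2.08 to 2.097-fold lower shares. Of these 5, 3 had the same counts of 354 and 247 reads. Within miR166, osa-miR166m (20566 and 15373 reads) and cme-miR166i (8547 and 6498 reads) were 1.95-fold and 1.92-fold lower, whereas the share of ath-miR166a-3p was 1.04-fold higher.

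The target list of the mixed ovules, taken here to be the degradome sample, addressed which genes the miRNAs may target. The list held 1084 pairs of 235 miRNA names with 902 genes. By family, miR396 had the most target genes (99), followed by miR482 (56), miR172 (51), miR166 (44) and miR858 (44). Most target genes (807) were listed for a single family, and 95 for 2 or more. Of the target genes, 797 (88.4%) passed the FPKM filter, against 49.0% of all listed genes. The table gives no strength of evidence per pair, so no pair was ranked.

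The expression of these targets was then compared between the stages. Of all 21308 compared genes, 1976 were at least 2-fold higher and 1462 at least 2-fold lower in PN. Of the 797 compared targets, 62 were at least 2-fold higher and 59 at least 2-fold lower in PN. Their median log2 difference of 0.07 lay at percentile 5.73 of random lists matched on expression, whose median was 0.11. Without the FPKM filter their median was 0.05 and lay at percentile 2.13, below the middle 95%. Of 43 family lists, 4 lay outside the middle 95% of random lists, where chance gives about 1.08 on each side. This holds if targets of a family vary as independently as random genes, which was not tested. The targets of miR828, known as a regulator of MYB genes and itself at 3 and 5 reads, had the highest median at 1.31, with 4 of 6 genes at least 2-fold higher and none lower (percentile 99.99). The targets of miR394, known for an F-box gene of the shoot meristem, had a median of 0.69, with 3 of 12 genes at least 2-fold higher (percentile 99.45). Both calls depended on the FPKM filter: without it, miR828 had a median of 0.06 over 9 genes (percentile 49.2) and miR394 one of 0.52 (percentile 96.1).

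Lower in PN were the targets of miR2118, with a median of -0.44 and 3 of 18 genes at least 2-fold lower (percentile 0.2). The name pgi-miR2118, with 1 read in all, carried 14 of the 23 target genes of this family. The targets of miR171, which regulates GRAS transcription factors, had a median of -0.20 over 28 genes (percentile 2.24; 3.75 without the filter). The targets of the families with the largest read sums stayed within the range of random lists. These were miR166 (median -0.07, percentile 5.62), miR396 (0.23, percentile 92.0) and miR167 (0.09, percentile 44.9). The single names miR2950 and novel_2 exceeded the largest names of miR396 and miR167. Their target lists lay near the lower edge of that range, with medians of -0.35 (percentile 4.3) and -0.18 (percentile 4.87). Of the miR396 targets, 8 were at least 2-fold higher, 5 lower and 78 within 2-fold.

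**Figure D3:**
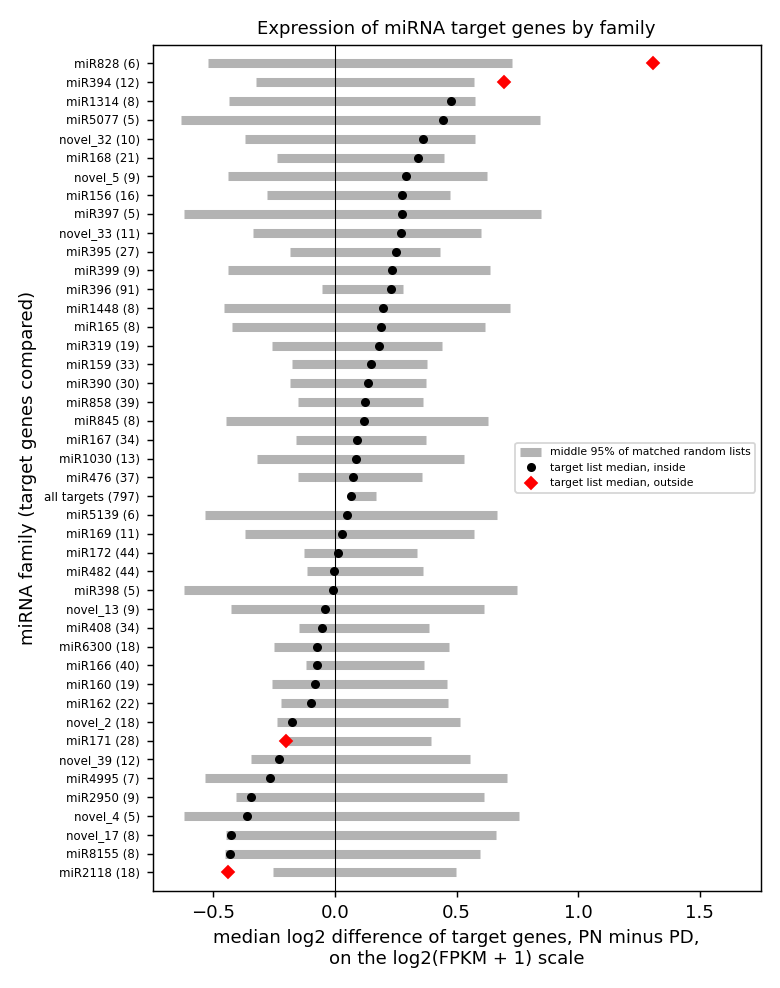
Median log2 difference (PN minus PD, log2(FPKM + 1)) of the target genes of each miRNA family with at least 5 compared genes (x axis); grey bars span the middle 95% of 10000 random lists matched on size and mean FPKM, and labels give the number of genes. Red diamonds mark the lists outside the grey bars, miR828 (1.31) and miR394 (0.69) above and miR171 (-0.20) and miR2118 (-0.44) below.

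A miRNA that lowers its targets would be expected to change opposite to them. Targets of the 5 families at least 2-fold higher in PN (29 family-gene pairs) had a median log2 difference of 0.06. Those of the 3 families at least 2-fold lower (42 pairs) had a median of 0.13. Of these 42 pairs, 34 were those of miR408, whose own target median of -0.05 lay below that of the higher families. The 5 targets of miR397 had a median of 0.28, and miR6478 had too few compared genes for a list. The inverse sign was therefore not seen for miR408, the lower family with most targets. The difference of -0.08 between higher and lower families was matched or exceeded in size by 41 of the 56 ways to assign the families to the 2 sets. The sign depended on the limits. The difference was 0.03 for families at least 1.5-fold higher or lower (5544 of 6435 arrangements as large) and 0.28 for families with at least 10 reads (1033 of 24310). The reported difference had the inverse sign but lay within the spread of the arrangements (SD 0.217), so an inverse relation of moderate size was neither shown nor excluded.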

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

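Taking a single member per family, counting identical names once and setting equal sums without the 10 most abundant genes were alternatives chosen after seeing the data. No paired analysis was possible because only 1 RNA-seq library per stage could be matched to its column, and for the same reason the leave-one-out fits, the other limma settings, camera and fry were not run; degradome categories, needed for 1 alternative, are not given. Counts of genes beyond 2-fold stayed within 1.5 times under every pseudocount, filter and scaling tried, from 1349 (mean FPKM of at least 5) to 2751 (pseudocount 0.1) higher and from 1069 to 1919 lower in PN under the same settings, although median-of-ratios and quantile scaling turned the excess of higher genes into an excess of lower ones (1591 against 1799 and 1631 against 1753). The read minimum moved the miRNA counts most: with at least 10 reads, 18 names were higher and 20 lower, and with no minimum 18 and 21, by construction from names of few reads. Family counts moved by at most 1 under median-of-ratios scaling (4 higher) and with a single member per family (4 higher, with miR398 lost). Among families with compared targets and at least 10 reads, 8 were at least 2-fold higher and 9 lower by ratio alone. Without the FPKM filter, 0 family target lists lay above and 1 below the middle range of random lists, and the list of all targets went from percentile 5.73 to 2.13, below that range; the median of miR828 then included 3 genes of low expression. The contrast between targets of higher and lower families was 0.28 with at least 10 reads, opposite in sign to that reported, and 1033 of 24310 arrangements of the families were as large; this is the reverse of what miRNAs lowering their targets would give, and the cause was not tested. It was 0.03 with a 1.5-fold limit. Depth limits the ratios of rare families, such as miR398 with an interval from 2.66 to 17.6, and the FPKM table gives only relative depth.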

Other observations

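The tests in this part were chosen only after the results were seen. The balance between the named arms of a miRNA differed between the libraries for miR166a and miR390a. Reads of ath-miR166a-5p per 100 reads of ath-miR166a-3p went from 0.0485 in PD to 0.172 in PN, and reads of ath-miR390a-3p per 100 reads of ath-miR390a-5p from 0.361 to 1.03. On the log2 scale these arm ratios were higher in PN by 1.83 (95% interval 1.36 to 2.29) and 1.51 (0.47 to 2.55).

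Their opposite arms had ratios of shares of 1.04 and 1.12. A loss of strand selection across the whole PN library may also give such a shift, and the miR396 names, taken over all pairs, did not decide it. Over 18 pairs of a 3p and a 5p name of miR396 with at least 50 reads, the log2 change ranged from -1.23 to 0.93, with a highest upper bound of 1.42. It was 0.02 for ath-miR396b-3p over ath-miR396b-5p and 0.85 for cca-miR396a-3p over ath-miR396a-5p. Arm names are not always reliable here, as zma-miR396g-3p and ath-miR396a-5p carried the same counts of 878 and 1158 reads. With 1 small RNA library per stage, a difference between the 2 libraries that is not the stage cannot be told apart from a change with pollination, which remains an untested hypothesis.

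The median gene was 0.11 higher in PN than in PD (bootstrap interval 0.10 to 0.12 over genes). A candidate explanation is that a few transcripts took a larger part of the FPKM total in PD. With both libraries rescaled to equal sums without the 10 most abundant genes, the median difference was 0.0526 (0.0423 to 0.0624), so this accounts for about as much of the shift as it leaves. A change in the many moderately expressed genes stays open and was not tested.

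Many target pairs belonged to miRNAs that were barely sequenced. Names with at most 1 read over both libraries held 202 of 1084 pairs (18.6%), and names with at most 10 reads held 432 (39.9%). hbr-miR476, with 0 reads in PD and 1 in PN, had 38 target genes, and ata-miR395b-3p, with the same counts, had 18. For 92 of the 202 pairs, those of hbr-miR476 among them, no name of the family had 10 reads. The other 110 pairs could be carried by an abundant member of the same family. The same gene was also listed for a name with at least 10 reads in 4 of them (3.64%, exact 95% interval 0.9995 to 9.05). This low share cannot decide the question, because a gene was rarely listed for more than 1 name of a family. All 1084 pairs made up 1030 family-gene pairs. Whether such pairs reflect cleavage at sites matched by sequence alone cannot be examined without the degradome counts, which were not analysed here.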
